A study of Homo sapiens with 11 samples.

How the data were processed

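NF-κB ChIP-seq of TNFα-induced A549 cells was deposited as 1 region list for each of 2 replicates. Per the labels' protocols, chromatin was crosslinked in 2 steps and precipitated with the antibody named f-6 (Santa Cruz), and libraries were made with Illumina reagents. Per the submitters' processing notes and the file headers, reads were aligned with Bowtie to hg19. The Bowtie version is not given in the sources used here. Per the file headers, the authors called regions with the findall program of ERANGE, version 3.141592653589, separately in each replicate and against 1 common input library. The headers give a spacing under 50 bp, a minimum above 4 RPM, a ratio to input above 5, a minimum peak of 0.5 and trimming at 10%. They also give a strand filter that kept regions with 25% to 75% of reads on the plus strand and at least 30% for the plus-strand reads left of the peak. This filter removed 161 regions in replicate 1 and 127 in replicate 2. Reads were shifted by 9 bp in replicate 1 and 4 bp in replicate 2, and reads mapping to several places were kept. When ChIP and input were exchanged, 53 and 50 regions were found, for which the headers give false discovery rates of 0.55% and 0.44%.

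The signal of a region was deposited in RPM, reads in the region per 1000000 reads of its ChIP library, at 1 decimal. RPM is a total and was not divided by the width of the region. The fold is the ratio of ChIP to the common input on a linear scale, per the file headers, and its pseudocount is not stated. The share of multireads, that is reads that map to several places, is a score that the authors' caller wrote in percent and that slightly exceeds 100 in places. The percent of reads on the plus strand, and of plus-strand reads left of the peak, are the authors' values. The peak height is a coverage signal at the listed peak position, as the authors' caller gives it. The p-value of each region was deposited too, taken from the background per the file headers, and was not used for ranking. Positions are hg19 coordinates as deposited. Whether they count from 0 or 1 is not stated, so a start can be 1 bp off. Depths are those of the headers, 24.7 M, 26.1 M and 29.7 M reads. At the median RPM a region rests on about 163 reads in replicate 1 and 177 in replicate 2. Treatment time is open: the labels' treatment protocol gives 12 hours of TNFα, both names of the lists give 30 minutes, and the library name in the header gives a time for replicate 1 only.

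Groups were taken from the sample labels. The tests and their alternatives were fixed before the data were examined, except those described as added. Regions sharing at least 1 bp were called shared. Chance overlap came from 1000 circular shifts of the replicate 2 list along each chromosome, whose span was taken from the largest coordinate in either list. Medians of shared and unshared regions were compared by permutation tests of 100000 resamples, with 95% intervals from 2000 bootstrap samples. Strength was compared on log2 RPM over regions paired one to one, by Pearson's r and Spearman's rho with 100000 permutations. Alternatives for the correlations used 10000. Since both lists share 1 input, folds were also correlated in 1000 draws that kept the input and broke the link between replicates. Each draw shuffled the replicate 2 RPM over regions and divided it by the implied input of each region. Where 1 region overlapped several, the pair holds that with the largest overlap. Shares have exact binomial 95% intervals and densities exact Poisson ones. Benjamini-Hochberg adjusted values were computed for the Fisher, chromosome and cluster tests of the closing section. The steps were tested on simulated lists of 9645 regions. An overlap made with 50% came back as 50.3% and one made with 90% as 90.1%, a correlation made with 0.8 came back as 0.80, and a list made without overlap gave 0.66%. A shift of the median by 25%, or 1.65 RPM, came back as 1.5 RPM.

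The implied input of a region was RPM divided by fold and by width, and its median per chromosome was taken over regions with at most 50% multireads. Regions with more than 50% multireads are called multiread-rich. They numbered 334 (3.46%) and 433 (3.78%). On contigs outside the assembled chromosomes lay 27 and 48 regions. Clusters were runs of at least 3 shared regions on chromosomes 1 to 22 and X with gaps of at most 10 kb, and chance came from 1000 draws that moved each region by up to 500 kb. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

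The rule for named regions took the 12 shared regions with the highest mean rank of RPM over both replicates. Its further parts named genes, and could not be applied. The plan also held 4 results that need sequence or genes of hg19: the share of regions with an NF-κB motif, polyamide target sites within motifs, distance to transcription start sites, and binding near 17 lists of genes. No hg19 genome or annotation was used here, and the gene table at hand is of another build, so these results and the 22 alternatives fixed for them were not run. The RNA-seq libraries and the input sample were not analysed here. Because 1 condition was analysed, no comparison between conditions was made.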

Results

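The series measured A549 cells, an established human non-small-cell lung cancer line, by chromatin immunoprecipitation sequencing (ChIP-seq) of NF-κB and by RNA sequencing. NF-κB is a family of transcription factors that enters the nucleus when a cell is exposed to inflammatory cytokines such as TNFα. In the RNA-seq, the design set TNFα-induced cells beside non-induced cells. Induced cells given a pyrrole-imidazole polyamide, a synthetic ligand of the DNA minor groove, or PS1145, an inhibitor of IκB kinase, formed the other groups. Of the 11 samples, 8 were RNA-seq libraries in 4 groups of 2, 1 was the ChIP input and 2 were NF-κB ChIP replicates from TNFα-induced cells. The region lists of both ChIP replicates were analysed. The RNA-seq libraries and the input were not analysed here, so the comparisons with non-induced cells, with the polyamide and with PS1145 were not made. The ChIP libraries held 24.7 M and 26.1 M reads, and both were called against the same input of 29.7 M reads. The labels do not say whether the replicates came from separate cultures, so the differences between them may be technical. The time of TNFα exposure before ChIP is open, because the treatment protocol gives 12 hours and the names of the deposited lists give 30 minutes.

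In TNFα-induced cells, NF-κB ChIP signal was listed at 9645 regions of the hg19 genome in replicate 1 and at 11459 in replicate 2. The regions covered 6.86 Mb and 7.28 Mb, and held 8.96% and 11.3% of the reads of their libraries. The median region was 648 bp wide in replicate 1 and 574 bp wide in replicate 2. Its signal, in reads per 1000000 reads of the library (RPM), was 6.6 RPM in replicate 1, or about 163 reads, and 6.8 RPM in replicate 2, or about 177 reads. The median fold over input was 17.8 and 20.7. At least 10 RPM was reached by 2525 regions of replicate 1 (26.2%) and by 3238 of replicate 2 (28.3%). Replicate 2 listed 1.19 times as many regions as replicate 1 from 1.06 times as many reads. Both lists begin at 4.0 RPM, where 1 region rests on about 98.8 reads in replicate 1 and 104 in replicate 2. At that depth the 95% Poisson interval runs from 3.26 to 4.88 RPM and from 3.26 to 4.83 RPM. These intervals cover counting error only, since reads copied by PCR are not independent molecules. Intervals of shares, medians and densities per Mb given further on treat the regions as independent and cover nothing but their number. The RPM, fold and positions are the authors' own values per region.

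Among regions shared by both replicates, the strongest NF-κB signal in each lay on chromosome 19 at 41426665 to 41428162 (hg19; regions shared by both lists are given with replicate 1 coordinates, and regions of 1 list with its own). It reached 193.1 RPM in replicate 1 and 257.3 RPM in replicate 2, a mean of 225 ± 45.4 RPM (SD, n = 2), and the listed peak positions were 5 bp apart. Reads that map to several places made up 11.6% and 10.4% of its signal. Of the 12 shared regions with the highest mean rank, 5 lay on chromosome 14. The strongest of these, at 94811703 to 94813358, had 169 ± 20.2 RPM (SD, n = 2), but reads that map to several places made up 47.1% and 45.2% of its signal. The next, at 35872223 to 35874886, had 160 ± 23.5 RPM (SD, n = 2) and no such reads. The other chromosome 14 regions lay close together, at 103576932 to 103579608 with 97.7 ± 18.3 RPM, at 103587446 to 103591574 with 100.2 ± 1.2 RPM, and at 103726279 to 103727735 with 94.5 ± 18.6 RPM (SD, n = 2 each).

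Chromosome 19 held another 2 of the 12 regions. That at 39892041 to 39895186 had 150 ± 13.1 RPM (SD, n = 2), and that at 45249888 to 45252744 had 92.5 ± 8.27 RPM (SD, n = 2). Chromosome 5 held 1 region, at 131831128 to 131834656, with 139 ± 10.6 RPM (SD, n = 2). Chromosome 17 held 1 at 38698397 to 38699803, with 99.8 ± 4.67 RPM (SD, n = 2), and chromosome 1 held 1 at 155096865 to 155097791, with 91.8 ± 15.8 RPM (SD, n = 2). The remaining region lay on 17_gl000205_random, a chromosome 17 contig of unknown position, at 84180 to 88571, with 108 ± 14.9 RPM (SD, n = 2). Its fold over input was 9.1 and 12.8, the lowest of the 12, whereas the median fold of the 12 in replicate 1 was 62.9. RPM was higher in replicate 2 at 10 of the 12 regions and lower at 2, which were those on chromosome 17 at 38698397 and on chromosome 14 at 103576932. Replicate 2 listed 2 regions where replicate 1 listed 1 in 2 of the 12 cases, and the pair holds 1 of them. On chromosome 14 at 103576932, replicate 1 had 110.6 RPM and the paired region of replicate 2 had 84.7 RPM, but both replicate 2 regions together had 106.7 RPM, so most of that difference and of its SD comes from where the region was divided. On chromosome 19 at 39892041, the paired region of replicate 2 had 159.1 RPM and both together had 167.3 RPM. The choice of the 12 rests on RPM, which is summed over the whole width of a region. In replicate 1 the 12 were 926 to 4391 bp wide, against a median of 651 bp over all paired regions. None of the 12 was among the 12 highest shared regions by fold over input, and 6 were among the 12 highest by peak height. No gene, exon or promoter is given for any region, because no hg19 annotation was used here.

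**Figure D1:**
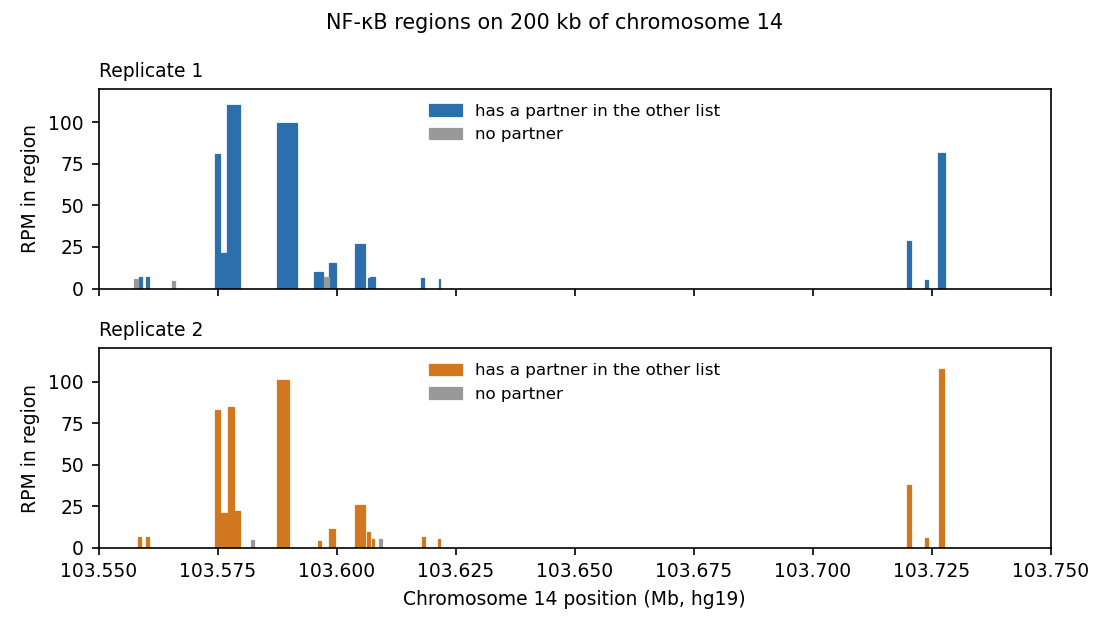
Map of chromosome 14 from 103.55 to 103.75 Mb (hg19), with replicate 1 above and replicate 2 below. Each bar spans 1 listed region along the horizontal axis and its height is the region's RPM; grey bars have no overlapping region in the other list. Both lists hold 19 regions in these 200 kb, of which 16 in replicate 1 and 17 in replicate 2 have a partner.

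The 200 kb of chromosome 14 from 103.55 to 103.75 Mb hold 3 of the 12 strongest regions. Both replicates listed 19 regions there, and their signals added up to 535.6 RPM in replicate 1 and 554.3 RPM in replicate 2. A partner in the other list was found for 16 of the 19 regions of replicate 1 and for 17 of the 19 of replicate 2.

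The first comparison asked how far the replicates placed NF-κB at the same positions. Of the replicate 1 regions, 8598 (89.1%, exact 95% interval 88.5% to 89.8%) overlapped a replicate 2 region by at least 1 bp. Of the replicate 2 regions, 8657 (75.5%, 74.7% to 76.3%) overlapped one of replicate 1. Among regions of at least 10 RPM the share was 99.0% in replicate 1 (2500 of 2525) and 98.3% in replicate 2 (3182 of 3238). Among weaker regions it was 85.6% and 66.6%. When the replicate 2 regions were shifted along each chromosome at random, a mean of 70.0 replicate 1 regions overlapped, with a highest value of 123 (permutation p = 0.001 for each list, one-sided, the smallest that 1000 shifts can give). Part of the overlap may come from the input that both lists share, which could not be separated here.

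**Figure D2:**
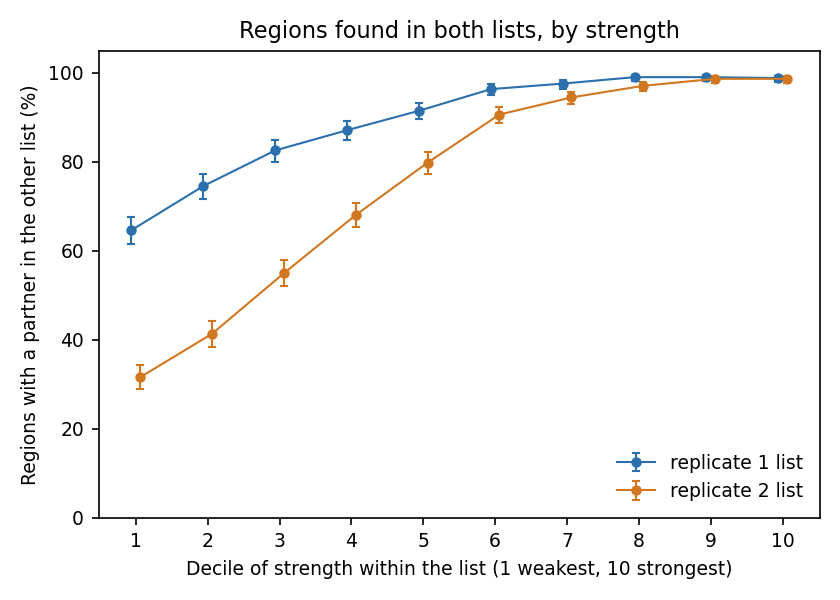
Share of regions with a partner in the other list, in percent, by decile of RPM within each list, from weakest (1) to strongest (10). Points are the 2 lists and bars are exact 95% binomial intervals; the share runs from 64.7% to 98.9% in replicate 1 and from 31.6% to 98.7% in replicate 2.

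Regions found in both lists were stronger than those found in 1. In replicate 1 the median was 7.1 RPM for the 8598 shared regions and 4.6 RPM for the 1047 others, a difference of 2.5 RPM (95% bootstrap interval 2.3 to 2.6). In replicate 2 it was 8.1 RPM for the 8657 shared regions and 4.7 RPM for the 2802 others, a difference of 3.4 RPM (3.3 to 3.5). Both differences had p = 1e-05 in a two-sided permutation test of 100000 resamples, the smallest it can give, over regions, which are not independent replicates. In the weakest decile of each list, 64.7% of replicate 1 regions and 31.6% of replicate 2 regions had a partner. In the strongest decile the shares were 98.9% and 98.7%.

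A few of the strongest regions were nevertheless listed in 1 replicate alone. These were picked out after their values were seen. The strongest region of the whole replicate 2 list, on chromosome 5 at 1081720 to 1083658, had 300.7 RPM and no partner, and 66% of its signal came from reads that map to several places. In replicate 1 the region on chromosome 10 at 47055788 to 47058828, the second strongest of that list with 186.9 RPM, had no partner either. Replicate 2 also listed 136.2 RPM on chromosome 15 at 93346705 to 93348042, where the nearest replicate 1 region was 1407 bp away. The share of plus-strand reads left of the peak, for which the caller required 30%, was 37.2% in the chromosome 5 region, 80.7% in the chromosome 10 region and 85.7% in the chromosome 15 region. Since a region absent from a list can have failed any of the caller's filters, absence from the list does not show that signal was absent.

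The second comparison asked how alike the replicates ranked the same regions. Across the 8494 regions that paired one to one, log2 RPM had a Pearson r of 0.892 and a Spearman rho of 0.826 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). These correlations are across regions, which are not independent replicates. Both lists hold only regions past the same minimum. RPM was higher in replicate 2 at 5998 of the 8494 regions (70.6%), with a median ratio of 1.15, and 7193 regions (84.7%) lay within 1.5-fold of each other. At 193 regions the replicates differed by more than 2-fold. The SD of the log2 ratio was 0.39. RPM was summed over regions bounded separately in each replicate, so differences in their bounds enter this spread. Fold over input gave r = 0.851, but both folds share 1 input. Shuffling the replicate 2 RPM between regions while keeping the input gave r = 0.401. The covariance of the log2 folds was 0.61 as observed and 0.41 after the shuffle, a difference of 0.20. The shuffle also broke any link between RPM and input within a region. The share of the agreement due to the common input can thus not be read from it. The covariance of log2 RPM, which uses no input, was 0.60.

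**Figure D3:**
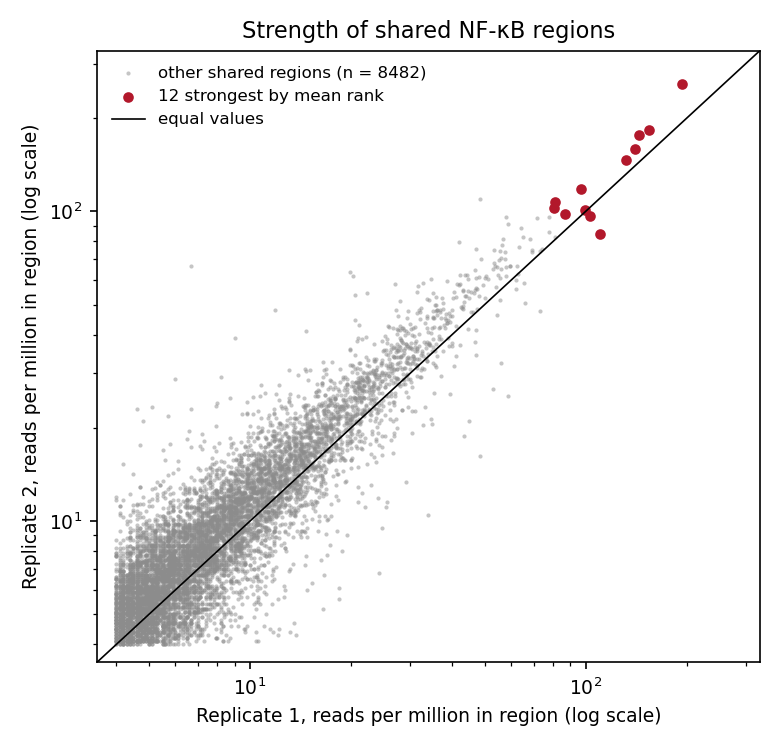
RPM of 8494 shared regions in replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale). Each point is 1 region, the 12 regions with the highest mean rank are in red and the line marks equal values; 70.6% of the regions have the higher value in replicate 2, including 10 of the 12.

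The listed peak positions of paired regions lay a median of 22 bp apart, and 78.0% were within 50 bp. At 104 of the 8494 pairs the positions were more than 500 bp apart. Among the 12 strongest regions the distance ran from 2 bp, on chromosome 14 at 94811703, to 254 bp, on chromosome 17 at 38698397. Paired regions were a median of 651 bp wide in replicate 1 and 601 bp in replicate 2, and 58.3% were wider in replicate 1.

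NF-κB regions were unevenly spread over the chromosomes. Chromosome 19 was densest, with 11.2 regions per Mb of the span covered by the lists in replicate 1 (exact 95% Poisson interval 10.3 to 12.0) and 13.6 in replicate 2 (12.7 to 14.6). Chromosome 17 followed with 10.6 (9.88 to 11.3) and 12.1 (11.4 to 12.9). Chromosome 13 was sparsest of chromosomes 1 to 22 and X, with 0.72 (0.56 to 0.92) and 1.1 (0.89 to 1.3). The ratio of chromosome 19 to chromosome 13 was 15.4 (12.0 to 19.8) in replicate 1 and 12.5 (10.1 to 15.3) in replicate 2. Of the 200 strongest shared regions, 30 (15.0%) lay on chromosome 19 and 29 (14.5%) on chromosome 17, which held 6.88% and 8.71% of all shared regions. This difference was not tested. The input level implied by RPM, fold and width at the listed regions also differed between chromosomes 1 to 22 and X, by up to 1.94-fold in replicate 1 and 1.88-fold in replicate 2.

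**Figure D4:**
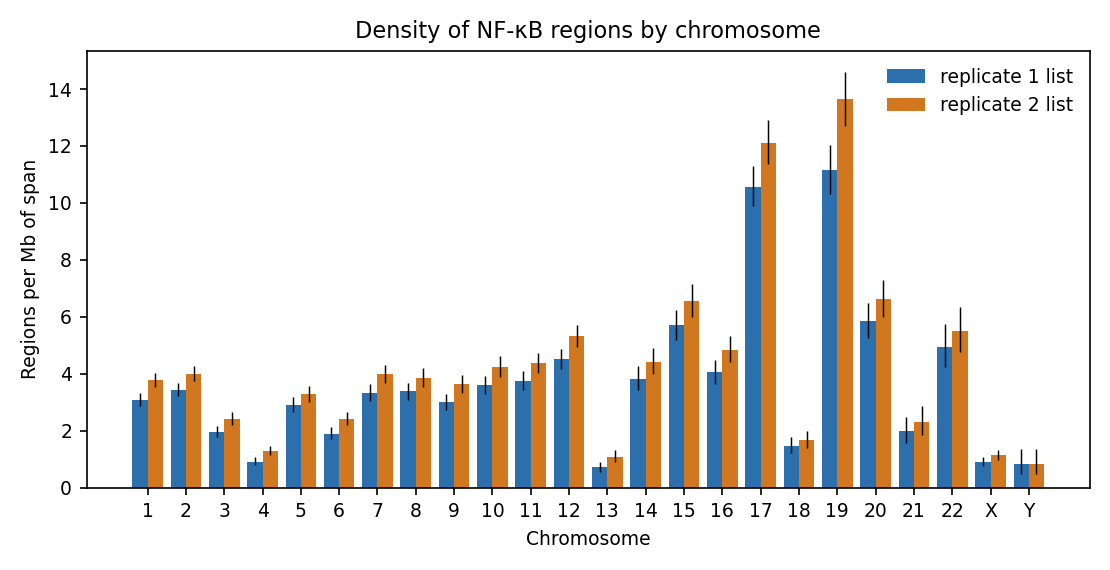
Listed regions per Mb of chromosome span for chromosomes 1 to 22, X and Y, in both lists. Bars are densities and lines are exact 95% Poisson intervals; chromosome 19 reaches 11.2 and 13.6 regions per Mb and chromosome 13 has 0.72 and 1.1.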

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

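The chance overlap from local moves, the alternatives without multiread-rich regions, the peak height and the region counts under both filters were added after seeing the data. Under all 30 alternatives run on the 8 main values, 16 of them planned, overlap stayed above chance, shared regions stayed stronger and both correlations stayed positive, each past its test, and region counts stayed within 1.5-fold. The counts could hardly have done otherwise, since their filters left 9311 or 9601 regions in replicate 1 and 11026 or 11394 in replicate 2. For the other values, passing asked only for the same direction with a small p-value. With this many regions that is a low bar, so the ranges that follow say more. The overlap ran from 80.3% to 89.4% of replicate 1 and from 67.6% to 81.3% of replicate 2. The lowest values came from requiring peaks within 100 bp. Pearson's r ran from 0.851 to 0.892 and Spearman's rho from 0.775 to 0.849. Without multiread-rich regions the difference in median between shared and other regions was 2.5 RPM and 3.3 RPM. Of the 12 strongest regions by RPM, 0 were among the 12 strongest by fold and 6 by peak height. The cause was not tested. Moving regions by 20 to 500 kb raised chance overlap from 70.0 to 208 of the 9645 replicate 1 regions. No paired analysis was possible because 1 group alone was analysed. Leaving out a replicate gives no value for overlap or correlation, which need both. The 22 alternatives fixed for motifs, polyamide sites, start sites and gene lists were not run, for lack of an hg19 genome here. Depth limits regions near 4 RPM, where about 98.8 and 104 reads stand behind a region.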

Other observations

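NF-κB regions lay in groups along the genome. Of 8454 shared regions on chromosomes 1 to 22 and X, 1744 (20.6%) stood in 458 clusters of at least 3 regions with gaps of at most 10 kb. Moving each region at random by up to 500 kb gave a mean of 91.9 clusters and at most 120 (permutation p = 0.001, one-sided, the smallest that 1000 draws can give, adjusted 0.001 over 4 tests). With moves of up to 100 kb the mean was 204, so the ratio to chance fell from 4.99 to 2.24 (permutation p = 0.001, adjusted 0.001). With gaps of at most 5 kb there were 319 clusters against a mean of 32.5 by chance (permutation p = 0.001, adjusted 0.001). Part of the excess is built in, because the caller can divide 1 stretch of signal into adjoining regions. With regions within 1 kb of each other joined first, 7783 were left. They stood in 289 clusters against a mean of 66.8 by chance with moves of up to 500 kb, a ratio of 4.32 (permutation p = 0.001, adjusted 0.001). Joining was not combined with moves of up to 100 kb, so the excess left under both limits is not known. Of the 458 clusters, 271 held 3 regions and 4 held 11, the highest number. These 4 lay, by their outer bounds in either list, on chromosome 14 at 103574346 to 103621749 (389.7 and 358.2 RPM summed in replicates 1 and 2), chromosome 15 at 67397534 to 67443252 (316.9 and 360.2 RPM), chromosome 5 at 150440188 to 150475526 (236.5 and 204.0 RPM) and chromosome 2 at 161061851 to 161098773 (134.0 and 125.6 RPM). Joined in the same way they held 7, 8, 6 and 8 regions. None of the 4 held a multiread-rich region.

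Among fixed windows of 500 kb, the 1 with the most shared regions was on chromosome 19 from 49000001 to 49500000, with 31. Chromosome 15 from 67000001 to 67500000 followed with 30, and chromosome 19 from 45000001 to 45500000 with 28. The last had the highest summed signal of the 10 fullest windows, 653.8 RPM in replicate 1 and 718.4 RPM in replicate 2. The clusters and windows were chosen for description after the lists were seen, and no explanation for them was tested.

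The tests of the 3 patterns that follow were chosen after their results were seen, except the test of DNA amount, whose expectation was set beforehand. Apart from DNA amount, on which its test could not decide, no biological explanation was tested for any of them.

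Regions listed in 1 replicate alone were mostly weak, and for those under 10 RPM a candidate explanation is the minimum of 4 RPM. The scatter of 2716 strong pairs was applied to each weak region, with or without a partner. It held both their mean log2 ratio of replicate 2 to replicate 1, 0.237, and the SD of that ratio, 0.386. Over all 8494 pairs the mean was lower, 0.189. The shift puts more replicate 2 regions and fewer replicate 1 regions under the minimum, so both totals rest in part on it. The test was not run without the shift. Of 8221 such regions in replicate 2, it put 2414 under the minimum. The ratio of this total to the 2746 regions without a partner was 0.879 (counting interval 0.847 to 0.913), past the bound of 0.5 set for this test. Of 7120 in replicate 1, it put 482 under the minimum. The ratio to the 1022 without a partner was 0.472 (0.444 to 0.502), an interval that spans the bound, so the question stays open there. Only totals were compared, so the test does not show that the regions put under the minimum are those without a partner. Of regions of at least 10 RPM without a partner, 11 of 25 in replicate 1 (44.0%) and 17 of 56 in replicate 2 (30.4%) had under 50% of plus-strand reads left of the peak, against 13.9% and 10.9% of those with a partner (odds ratios 4.88 and 3.55, Fisher's exact test, two-sided, p = 0.00028 and 8.1e-05, adjusted 0.00028 and 0.00016 over 2 tests), which is consistent with loss of some partners to the strand filter. These strong regions without a partner were also wider, with medians of 1383 against 866 bp and 1086 against 766 bp (permutation p = 1e-04 each, the smallest that 10000 resamples can give), so how regions were bounded stays open beside the filter, and the chromosome 10 and chromosome 15 regions without a partner, at 186.9 and 136.2 RPM, had 80.7% and 85.7%, far from the limit of 30%, which gives the filter no support there.

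The density of regions differed by 15.4-fold in replicate 1 and 12.5-fold in replicate 2 between the densest and the sparsest chromosome, 19 and 13. More DNA of a chromosome in these cells could raise its counts past a fixed RPM minimum, and density did follow the implied input over 23 chromosomes (Spearman rho 0.727 and 0.726, permutation p = 0.0001 each, adjusted 0.0002 over 6 tests; Pearson r 0.732 and 0.729, permutation p = 2e-05 each, adjusted 6e-05). Without the 2 chromosomes farthest from the median, r was 0.711 and 0.808. Raising the minimum in proportion to the implied input left a ratio of densest to sparsest of 7.67 (6.17 to 9.52, chromosome 19 over X) in replicate 1 and 7.20 (5.75 to 9.01, chromosome 19 over 13) in replicate 2, far above the bound of 2 set for it, which argues against DNA amount as the whole cause, and rho was then 0.478 and 0.521 (permutation p = 0.0204 and 0.0117, adjusted 0.0204 and 0.014). The implied input is known at listed regions alone and is not a direct measure of DNA amount, so the cause of the difference stays open.

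Multiread-rich regions were a small share of both lists, but they include the strongest region of replicate 2. Of these regions, 70 of 334 in replicate 1 (21.0%) repeated the width, RPM and fold of another region in the list, as did 93 of 433 in replicate 2 (21.5%). Among other regions the shares were 0.38% and 0.77% (odds ratios 70.3 and 35.2, Fisher's exact test, two-sided, p = 1.0e-78 and 2.5e-86, adjusted 1e-78 and 5e-86 over 2 tests). Such repeats can arise from 1 signal listed at several places that share sequence. The class is itself defined by reads that map to several places. An excess of repeats was therefore likely beforehand and is weak support. An instance is a pair of regions of 1277 bp on the contig Un_gl000220, both with 72.6 RPM and 99.7% multireads in replicate 2. The repeats concern about 1 in 5 multiread-rich regions, and for the others the explanation stays open. Regions that repeat one another were each counted in the Fisher tests. They are not independent, so those p-values are too small.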
